A study of Rattus norvegicus with 12 samples.

How the data were processed

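The samples were 12 rat sciatic nerve stumps in 4 groups of 3. Per the labels, the groups were Control, the conduit CC4:2, the conduit CC4:4 and VP4:2, a CC4:2 conduit loaded with verteporfin. The labels did not say what the control stumps received, how long after surgery tissue was taken, whether the 3 stumps of a group came from separate animals, or what the numbers in 4:2 and 4:4 stand for beyond a shape of the truncated cone. The p-values therefore measure the spread between these samples, which may be technical in part. Per the labels' protocols, poly(A) RNA was made into stranded libraries and read as pairs of 150 bases. Per the labels, replicates 1 and 2 of every group (8 samples) were read on a NovaSeq X Plus and replicate 3 (4 samples) on a DNBSEQ-T7, so platform and group were balanced.

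The deposited values were expected counts per gene, which need not be whole, with no normalization recorded. Per the submitters' processing notes, the authors used HISAT2, StringTie, RSEM and DESeq2. Their versions, the roles of each, the genome build and the annotation were not given in the sources used here. The 12 deposited files were identical tables of all samples, so 1 was read and 11 were not used. It held 30562 genes, of which 4367 had no symbol. None of the Ensembl identifiers (0) matched the reference table at hand, so symbols came from the deposited table and no coordinates are given. Between 9.44% and 11.12% of the values in a sample, zeros included, were not whole. All values were rounded to whole numbers before testing. Totals ranged from 13763093 to 18632300 counts per sample, with 17565 to 17988 genes detected. No 2 replicates differed by as little as sampling noise, since chi-square per degree of freedom between replicates of a group was 49.7 to 336.

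Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Scaling used TMM, low genes were removed with filterByExpr, and 15712 genes were tested. All 12 samples entered 1 fit with a term per group and 8 residual degrees of freedom, and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with a standard error (SE) worked back from the test. It is the size of the fold change divided by the square root of the quasi-likelihood F statistic. Levels are given as TMM-scaled CPM with the SD over 3 samples. Where all libraries of a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group, which covers counting error only. Near-identical copies of a gene, among them immunoglobulin genes and ribosomal pseudogenes, can share reads, so their values are uncertain.

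The 34 gene lists (509 genes, of which 13 had no unique name in the table) were fixed before the data were examined, as were the comparisons, tests, alternative settings and the rule for named genes. Lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. A list needed 5 tested members. The camera test with an estimated correlation and fry were run beside it. Counts of list members called over all genes stand beside the count adjusted over the list alone. The YAP target score was the mean log2 CPM of 21 target genes in a sample, compared by an exact two-sided permutation test. With 3 against 3 samples that test cannot give a p below 0.1.

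Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, a usual symbol and no overlap between the 2 groups, up to 4 members of smallest p from a list that passed or had 2 called members, and always Yap1, Wwtr1, Ccn1, Ccn2 and Ankrd1. Where fewer than 5 genes qualified, the 10 genes of smallest p took the place of the largest changes. The text prints a part of the genes this rule gave. That part was chosen after the values were seen, and for VP4:2 against CC4:2 also after it was seen which calls held with libraries left out, so counts of calls that held are given over all called genes and over all called genes of the rule. Some results of 2 genes that the rule gave are not reported here. In addition, a gene named only as the odd member of a list was likewise picked after its value was seen.

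The gene test was checked on simulated counts drawn from the real means and library sizes, with 100 of the 15712 genes changed 2-fold and 100 changed 4-fold per comparison. It recovered 21 and 71 of them for CC4:2 against Control, 24 and 79 for CC4:4 against Control, 25 and 72 for VP4:2 against CC4:2, 24 and 67 for CC4:2 against CC4:4, and 24 and 72 for VP4:2 against Control. False calls made up 4.2%, 8%, 4%, 1.1% and 2% of the calls, in the same order. The camera test found a shifted myelin list and 0 other lists in each simulation. Genes were drawn independently there, so the simulations could not show false list calls that arise from genes moving together.

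The alternative settings fixed then were RLE and upper quartile scaling, no filter and a strict filter (10 counts in every sample of at least 2 groups), DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, only the 6 samples compared, each library left out in turn, the replicate number as a block, platform as a covariate, the NovaSeq samples alone, and a minimum of 2-fold. The skeletal muscle list as a covariate and the removal of immunoglobulin genes were added after seeing the data. The DNBSEQ-T7 gave 1 sample per group, too few for a test within that platform. Replicate numbers were checked for pairing by correlating deviations from group means. For VP4:2 with CC4:2 same-numbered samples gave 0.12, 0.28 and 0.43 (across genes), all above 0.1, so they were read as paired. The main calls of that comparison still came from the fit without a block. The blocked count is given beside them, and blocked values stand beside printed calls that the block ended. This pairing is an assumption, since no source stated it and samples of unlike number gave -0.42 to 0.18. Replicate 3 was the DNBSEQ-T7 sample in every group, so its 0.43 may reflect platform. In no other comparison did all 3 pairs exceed 0.1. Comparisons that share libraries were set beside 20 simulations of unchanged groups.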

Results

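Poly(A) RNA of rat sciatic nerve stumps was counted per gene in 12 samples, 3 each from control stumps (Control), stumps in a truncated-cone conduit labelled 4:2 (CC4:2), stumps in a conduit labelled 4:4 (CC4:4), and stumps in a 4:2 conduit loaded with verteporfin (VP4:2), a compound that blocks the binding of the mechanosensitive coactivator YAP to its TEAD partners. Totals were 18632300, 13784090 and 13763093 counts in Control, 17440338, 17585176 and 17138859 in CC4:2, 16544428, 17254998 and 16831954 in VP4:2, and 17336892, 16838385 and 16118793 in CC4:4. The first principal component held 58.4% of the variance and ran from the CC4:2 samples through VP4:2 to CC4:4 and Control. Control replicate 1 stood apart on the second component (11.6% of the variance), at 84.9 against -34.1 and -55.9 for the other controls. Values below are log2 fold changes ± SE with 3 samples per group and edgeR adjusted p, unless another test is named.

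**Figure D1:**
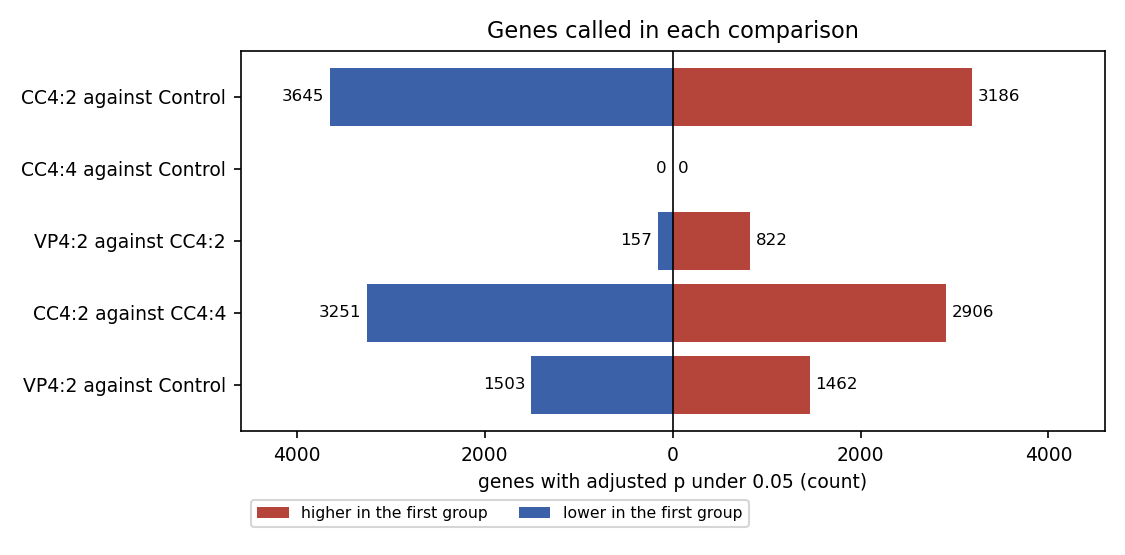
Bars give the number of genes called in each comparison (horizontal axis, count at an adjusted p under 0.05 in edgeR's quasi-likelihood test), split by direction. CC4:2 against Control had 3186 genes higher and 3645 lower, and CC4:4 against Control had 0 of either.

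The first comparison asked what the CC4:2 conduit changed in the stump. CC4:2 stumps held more myelin, Schwann cell, lipid synthesis and fat cell transcripts than control stumps and fewer cytokine, macrophage, neutrophil and lymphocyte transcripts, while mast cell markers did not fall. All 17 measured myelin genes rose, with a median of 3.10, among them the compact myelin protein gene Pmp22 (2.99 ± 0.51, adjusted p = 0.0012, from 438 ± 296 to 3480 ± 1610 CPM) and Mag, which encodes an adhesion protein of the myelin sheath (3.33 ± 0.62, adjusted p = 0.0018). All 19 cytokine and chemokine genes but 1 fell, led by the neutrophil attractant Cxcl2 (-9.65 ± 0.70, adjusted p = 1.8e-05) and the inflammatory cytokine Il1b (-6.33 ± 0.46, adjusted p = 1.8e-05, from 313 ± 150 to 3.87 ± 1.04 CPM). Control replicate 1 carried part of the rise, with a myelin index (mean log2 CPM of the list) of 3.06 against 6.32 and 5.59 in the other controls. The index difference of 3.43 became 2.47 without it, and that of the pan-Schwann markers went from 3.05 to 2.26.

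The edgeR test called 6831 of 15712 genes (43.5%), 3186 higher and 3645 lower in CC4:2. Of 10 pan-Schwann cell markers, 9 rose and all 10 did so adjusted over the list alone, including S100b (3.25 ± 0.50, adjusted p = 6.3e-04) and Foxd3, a neural crest factor (4.18 ± 0.82, adjusted p = 0.0024). The camera test gave the myelin list an adjusted p of 2.7e-07 and the Schwann list 9.2e-05, and both lists had an adjusted p = 0.38 with an estimated correlation. Of 19 cholesterol and fatty acid synthesis genes, 16 rose and 17 did so adjusted over the list alone (list adjusted p = 7.5e-08, and adjusted p = 0.21 with an estimated correlation). They included Hmgcs1, an early enzyme of sterol synthesis (2.34 ± 0.21), and Acaca, which commits carbon to fatty acids (1.74 ± 0.18). All 12 adipocyte markers rose, with a median of 4.06 (list adjusted p = 2.8e-05, and adjusted p = 0.38 with an estimated correlation), such as the fat hormone genes Adipoq (4.22 ± 0.78) and Lep (4.45 ± 0.74). Of 10 nerve fibroblast markers 7 rose and 3 were not called (list adjusted p = 0.0033, and adjusted p = 0.32 with an estimated correlation). Of 6 perineurial markers 5 rose, such as the integrin gene Itgb4 (3.65 ± 0.59), while the mesothelial gene Msln fell by 2.70 ± 0.30 (list adjusted p = 0.04, and adjusted p = 0.21 with an estimated correlation). Of 7 pericyte markers 4 rose (list adjusted p = 0.034, and adjusted p = 0.56 with an estimated correlation). The pericyte list lost its call without Control replicate 2 (0.055), Control replicate 3 (0.066) or CC4:2 replicate 2 (0.071).

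Of 20 macrophage markers 16 fell and 18 did so adjusted over the list alone, among them the lysosomal gene Cd68 (-2.67 ± 0.19, adjusted p = 1.8e-05) and Gpnmb (-2.55 ± 0.24). Of 9 neutrophil markers 8 fell, such as the calprotectin gene S100a9 (-6.00 ± 0.55) and the cytokine receptor gene Csf3r (-4.69 ± 0.34), while the granule enzyme gene Mpo rose by 3.23 (adjusted p = 0.0063). The macrophage list had an adjusted p of 7.5e-08, the neutrophil list 2.8e-05 and the cytokine list 1.2e-11, and each had an adjusted p = 0.15 with an estimated correlation. All 15 T and NK cell markers fell, including the T cell receptor gene Cd3e (-4.15 ± 0.40), and all 12 B and plasma cell markers fell, including Cd79a (-5.00 ± 0.70). The T and NK list had an adjusted p of 2.7e-08 (adjusted p = 0.21 with an estimated correlation) and the B and plasma list 5.3e-06 (adjusted p = 0.38 with an estimated correlation). Immunoglobulin genes recognised by symbol took 2.17%, 10.57% and 12.38% of the counts in the controls and 0%, 0.03% and 0.11% in CC4:2. Any among the 4911 genes without a unique symbol were not counted, here or below. Of 23 cell cycle genes 20 fell and Tyms rose by 0.55 (list adjusted p = 7.8e-07, and adjusted p = 0.36 with an estimated correlation). Of 11 genes of the NRF2 and haem response 5 fell, led by the haem-degrading enzyme gene Hmox1 (-3.61 ± 0.22, list adjusted p = 0.036, and adjusted p = 0.21 with an estimated correlation). That list lost its call without Control replicate 1 (0.071), and Tyms lost its call without Control replicate 2 (0.075) or 3 (0.092) or CC4:2 replicate 1 (0.053) or 3 (0.13).

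Of 19 genes of pain mediators and nociceptor channels, 11 fell and 5 rose (list adjusted p = 0.033, and adjusted p = 0.21 with an estimated correlation). The genes that fell included Il1b, Tnf (-3.80 ± 0.29), Ccl2 (-3.35 ± 0.32) and Cxcl1 (-6.30 ± 0.55), all inflammatory mediators. Those that rose were the growth factor gene Ntf3 and the channel genes Trpv1, P2rx3, P2rx7 and Scn9a, the last of which lost its call without CC4:2 replicate 1 (0.054) or 3 (0.051). Matrix protease genes were mixed, with 8 lower, 2 higher and 7 not called of 17 (list adjusted p = 0.12). The collagenase gene Mmp13 fell by 10.44 ± 1.07 and the protease inhibitor gene Timp3 rose by 1.61 ± 0.19. Lists whose camera test did not pass were those of repair Schwann cell genes (8 higher and 3 lower of 15, adjusted p = 0.059), fibrous matrix (4 higher of 24, 0.083), mast cells (4 higher of 10, 0.063), endothelium (3 higher of 13, 0.061), interferon-stimulated genes (5 lower of 15, 0.063) and angiogenesis factors (4 higher of 14, 0.11). The same held for hypoxia and glycolysis (3 higher and 6 lower of 15, adjusted p = 0.41), immediate early genes (4 lower of 13, 0.35), oxidative phosphorylation (2 higher and 5 lower of 17, 0.64), neuronal transcripts (3 higher and 2 lower of 12, 0.64) and cartilage and bone (3 higher and 1 lower of 12, 0.53). No list call was made for skeletal muscle (0 called of 13, adjusted p = 0.39), red blood cells (0 of 5, 0.61), TGF-beta signalling (4 higher and 4 lower of 14, 0.64) or smooth muscle contractile genes (1 higher of 13, 0.68). In the TGF-beta list the mean was -0.02 while the median and the test were upward, and in the smooth muscle list both median (-0.10) and mean (-0.15) were below 0 while the test pointed up.

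Among genes of the YAP pathway, Yap1 (ENSRNOG00000005933) rose by 0.88 ± 0.20 (adjusted p = 0.0059, 188 ± 4.78 against 102 ± 35.8 CPM) and its paralog Wwtr1 (ENSRNOG00000016617), which encodes TAZ, by 1.40 ± 0.24 (adjusted p = 0.0013). In the NovaSeq samples alone Yap1 was at 0.76 and was not called (adjusted p = 0.081), and with a library left out it ran from 0.76 to 1.21. Of 19 Hippo pathway components 10 rose, among them the transcription factor gene Tead1 (1.42 ± 0.17) and Vgll3 (1.42 ± 0.17), and 2 fell, among them the kinase gene Stk4 (-1.14 ± 0.19). That list had an adjusted p of 0.0027 (adjusted p = 0.36 with an estimated correlation). Of 20 focal adhesion and mechanosensing genes 8 rose, including the stretch-gated channel gene Piezo2 (1.89 ± 0.21) and Vcl, which encodes vinculin (1.28 ± 0.19; list adjusted p = 0.026, and adjusted p = 0.56 with an estimated correlation). The focal adhesion list lost its call without Control replicate 2 (0.055) or CC4:2 replicate 2 (0.08). Of 21 YAP/TAZ-TEAD target genes 10 rose, such as the receptor kinase gene Axl (1.38 ± 0.17), 4 fell, such as the kinase gene Nuak2 (-1.29 ± 0.17), and 7 were not called (list adjusted p = 0.063). The classical targets Ccn1 (ENSRNOG00000014350; -0.35 ± 0.53, adjusted p = 0.63), Ccn2 (ENSRNOG00000015036; -0.29 ± 0.46, 0.64) and Ankrd1 (ENSRNOG00000018598; -1.51 ± 1.02, 0.25) were not called. The mean log2 CPM of the 21 targets was 5.87 ± 0.18 (SD, n = 3) in CC4:2 and 5.45 ± 0.27 in Control (exact two-sided permutation p = 0.2). These were whole stumps whose immune and Schwann cell markers also differed. A change in cell mix could therefore not be told apart from regulation within cells, here or in the comparisons below.

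**Figure D2:**
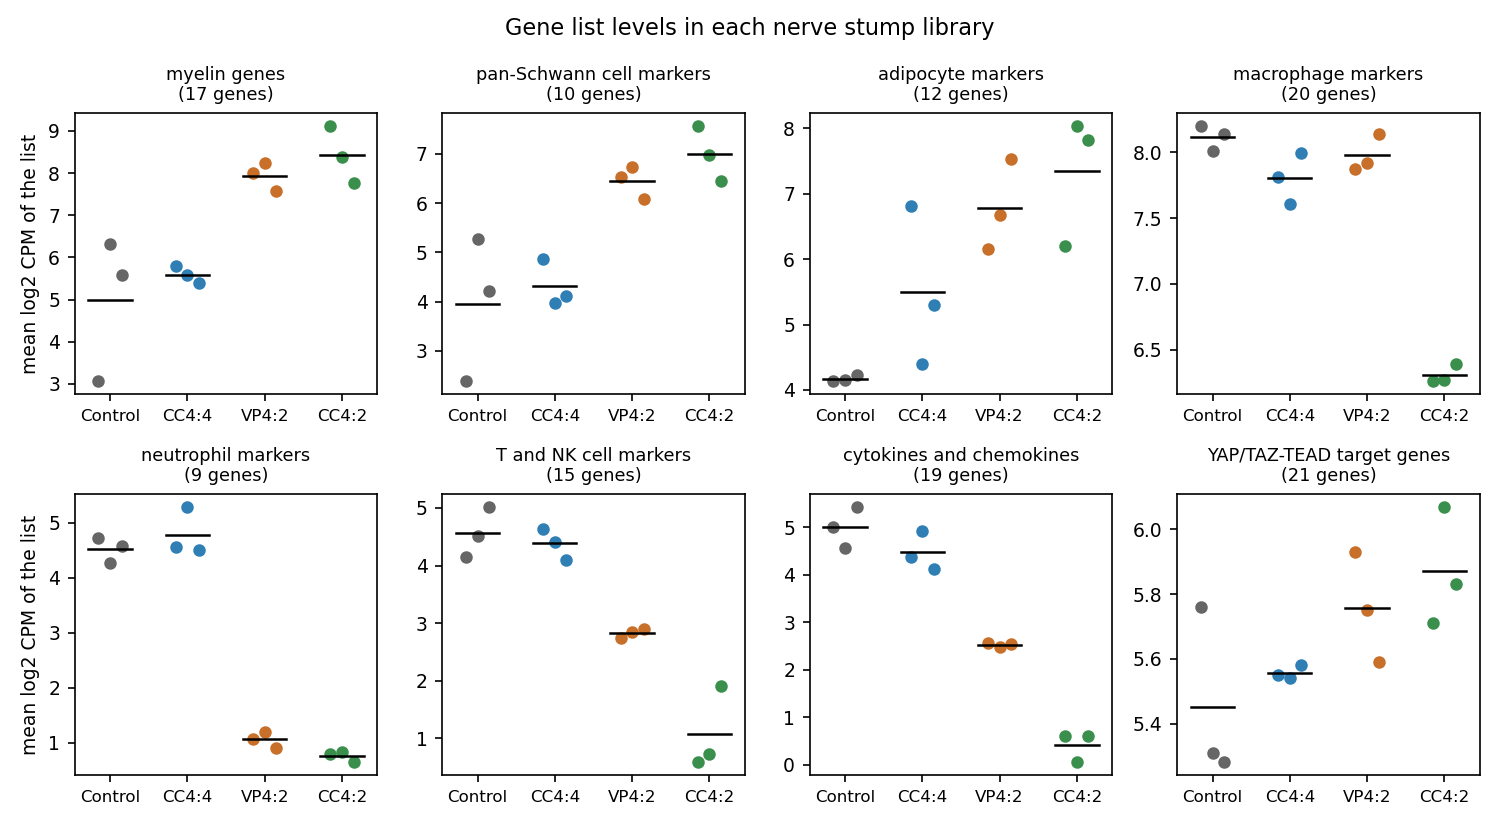
Each point is 1 library, and the vertical axis is the mean log2 CPM over the genes of a list, with a line at the mean of the 3 libraries of a group. Macrophage markers averaged 8.12 in Control, 7.81 in CC4:4, 7.98 in VP4:2 and 6.31 in CC4:2, while neutrophil markers averaged 4.53, 4.78, 1.06 and 0.76.

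The largest rises in CC4:2 were in Klk10, a kallikrein gene (at least 36.9-fold higher, with 0 counts in Control), Alb, the serum albumin gene (6.64 ± 2.13), Serpina12, which encodes the fat hormone vaspin (5.74 ± 1.5, adjusted p = 0.011, and 4.15 to 8.66 with a library left out), Elovl2 (5.65 ± 1.57) and the calcium-binding protein gene Calb1 (5.60 ± 1.19). Alb lost its call without Control replicate 1 (adjusted p = 0.073), 2 (0.074) or 3 (0.08) or CC4:2 replicate 2 (0.12), and Elovl2 without Control replicate 3 (0.05) or CC4:2 replicate 1 (0.08). With a library left out Alb ran from 4.45 to 8.66 and Elovl2 from 3.01 to 8.54. Serpina12 kept its call with each library left out (0.0079 to 0.042) but not in the NovaSeq samples alone (0.065), where Alb (0.11), Elovl2 (0.051) and Hspa1a (0.058) were not called either. Of the 134 called genes that the naming rule gave for CC4:2 against Control, 101 were called in the NovaSeq samples alone. The largest falls lay in immunoglobulin genes such as Ighg1 (-9.96 ± 2.01), in Mmp13, in the chemokine gene Cxcl6 (-8.98 ± 0.74), in the neutrophil-associated peptide gene Prok2 (at least 175-fold lower) and in the heat shock gene Hspa1a (at least 125-fold lower), the last 2 with 0 counts in CC4:2. The NovaSeq samples alone gave 1517 higher and 1705 lower genes, and 3148 of these 3222 were among the 6831. Of the 6831 calls in CC4:2 against Control, 4575 were made with each of the 6 libraries left out in turn and 2890 in all 19 settings. Only the 6 samples compared gave 4359 genes, and a change of at least 2-fold left 4128. Another split of the same 6 samples also passed 17 lists, so the list test with its preset correlation is weak evidence here. The fry test passed all 17 lists of the real split in the same direction, while 0 passed camera with an estimated correlation.

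The second comparison asked the same of the 4:4 conduit. CC4:4 stumps lay nearer to control stumps than CC4:2 stumps did in their myelin and immune transcripts. The index differences were 0.6 (SE 0.99) for myelin genes, -0.31 (SE 0.12) for macrophage markers and 0.25 (SE 0.29) for neutrophil markers. The median fold changes of these lists were 0.15, -0.27 and 0.26. Adipocyte markers showed the largest list median, at 1.90, but their index differed between libraries, at 6.82, 4.39 and 5.30 in CC4:4 against 4.13, 4.15 and 4.23 in Control. Its difference of 1.34 became 0.68 without CC4:4 replicate 1. Adipoq stood at 148 ± 143 CPM in CC4:4 and 28.8 ± 10.1 in Control (2.36 ± 0.72, adjusted p = 0.93). The 2 genes of smallest p, RGD1561722 and LOC100911032, had the same counts in every library and may share their reads. Each stood at 117 ± 71.8 CPM in CC4:4 and 1.27 ± 1.12 in Control (6.60 ± 1.06, adjusted p = 0.93). Among the 10 genes of smallest p were also the prostaglandin synthase gene Ptgs2 (-1.68 ± 0.35), the complement regulator gene Cfi (1.02 ± 0.21) and the activin receptor gene Acvr1b (-0.54 ± 0.11), each with an adjusted p = 0.93.

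The edgeR test called 0 of 15712 genes, with 831 at an unadjusted p under 0.05. DESeq2 called 10 genes, 5 in each direction, limma-voom called 0, and edgeR on the NovaSeq samples alone called 0 (349 at an unadjusted p under 0.05). Leaving out Control replicate 1 gave 306 genes, 139 higher and 167 lower, and leaving out Control replicate 3 gave 1. The camera test with its preset correlation passed 10 lists upward and 4 downward, but 0 passed with an estimated correlation and 0 with fry. The upward lists included fibrous matrix (median 0.53, adjusted p = 4.4e-07), adipocytes (6.9e-07) and endothelium (5.5e-06), each with an adjusted p = 0.41 with an estimated correlation. None of their 49 members was called, although 6 adipocyte markers were higher when adjusted over the list alone. The downward lists were macrophages (5.9e-05), cytokines (3.4e-04) and hypoxia and glycolysis (0.043, not called without Control replicate 2 at 0.055 or 3 at 0.2, or CC4:4 replicate 1 at 0.07 or 3 at 0.22), each with an adjusted p = 0.41 with an estimated correlation, and pain mediators (0.003, and adjusted p = 0.24 with an estimated correlation). The myelin list passed upward (0.012, and adjusted p = 0.71 with an estimated correlation), but its direction turned without Control replicate 1 (adjusted p = 0.08), and it was not called without CC4:4 replicate 1 (0.089) or 2 (0.063). Yap1 (0.26 ± 0.20, adjusted p = 0.98) and Wwtr1 (0.42 ± 0.24, 0.95) were not called. The YAP target score was 5.55 ± 0.02 in CC4:4, 0.10 above Control (exact two-sided permutation p = 0.4), with the mean fold change of the targets at -0.01 and the median at 0.02. In the skeletal muscle list (median -0.86) and the interferon list (median -0.29) median and mean were below 0 while the test pointed up, with adjusted p of 0.22 and 0.93.

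The difference between the conduits was tested directly. CC4:2 stumps differed from CC4:4 stumps much as they did from control stumps, with higher Schwann cell and myelin transcripts and lower immune transcripts. All 17 myelin genes were higher in CC4:2, with a median of 2.99, among them Egr2, the transcription factor that drives myelination (2.51 ± 0.39, adjusted p = 8.7e-04), and all 10 pan-Schwann markers. All 15 T and NK cell markers, all 12 B and plasma cell markers, 8 of 9 neutrophil markers, 13 of 20 macrophage markers and 18 of 19 cytokine genes were lower, such as Il1b (-5.74 ± 0.45), Cd68 (-2.34 ± 0.19) and Csf3r (-4.51 ± 0.34). Immunoglobulin genes took 5.63%, 11.34% and 6.54% of the counts in CC4:4.

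The edgeR test called 6157 genes, 2906 higher and 3251 lower in CC4:2. Of 23 cell cycle genes 21 were lower, including Rrm2, which encodes a subunit of ribonucleotide reductase (-3.32 ± 0.30). Of 12 adipocyte markers 4 were higher and 9 adjusted over the list alone, with Lep at 2.61 ± 0.67. Cidec, a lipid droplet gene (1.95 ± 0.64, adjusted p = 0.032), lost its call without CC4:2 replicate 2 (0.092) or 3 (0.072) or CC4:4 replicate 2 (0.1) or 3 (0.1). With a library left out Lep ran from 2.19 to 3.53 and Cidec from 1.56 to 3.13, and in the NovaSeq samples alone neither Lep (0.097) nor Cidec (0.2) was called. Wwtr1 rose by 0.99 ± 0.24 (adjusted p = 0.0089), as did Tead1 (1.33 ± 0.17) and Piezo2 (1.45 ± 0.20). Yap1 was called (0.62 ± 0.20, adjusted p = 0.034) but not without CC4:2 replicate 1 (0.075), 2 (0.064) or 3 (0.063) or CC4:4 replicate 1 (0.061) or 2 (0.1), nor in the NovaSeq samples alone (0.11). Of the YAP/TAZ-TEAD targets 10 were higher and 2 lower of 21 (list adjusted p = 0.14). The target score was 0.31 higher (exact two-sided permutation p = 0.1, the smallest it can be), at 5.71, 6.07 and 5.83 in CC4:2 and 5.55, 5.54 and 5.58 in CC4:4. The camera test passed 15 lists, with adjusted p of 1.6e-06 for myelin (adjusted p = 0.45 with an estimated correlation), 5.0e-12 for cytokines (0.19 likewise) and 4.5e-09 for the cell cycle (0.24 likewise), and 0 of the 15 passed with an estimated correlation. Genes of cholesterol and fatty acid synthesis (15 higher of 19, adjusted p = 1.6e-06), Hippo components (9 higher and 2 lower of 19, 0.023) and nerve fibroblast markers (5 higher of 10, 0.012) passed upward, with an adjusted p = 0.24, 0.45 and 0.36 with an estimated correlation. Matrix proteases passed downward (9 lower and 1 higher of 17, 0.027, and adjusted p = 0.75 with an estimated correlation), but not without CC4:2 replicate 1 (0.058) or CC4:4 replicate 3 (0.051). The NovaSeq samples alone gave 1425 higher and 1808 lower genes, of which 3146 were among the 6157. Of the 128 called genes that the naming rule gave, 93 were called there. In CC4:2 against CC4:4 a change of at least 2-fold left 3590 genes, and 3886 calls were made with each of the 6 libraries left out in turn and 2752 in all 19 settings.

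The third question was what verteporfin changed in the 4:2 conduit, when YAP binding was its target. With verteporfin, macrophage, chemokine and matrix protease transcripts were higher than in the unloaded conduit, while the neutrophil, myelin and pan-Schwann lists had 0 called genes. Of 20 macrophage markers 15 rose and 17 did so adjusted over the list alone, among them Gpnmb (3.04 ± 0.24, adjusted p = 1.2e-04, from 355 ± 72.6 to 2920 ± 535 CPM), Cd68 (2.35 ± 0.19, adjusted p = 1.3e-04), the integrin gene Itgam (2.33 ± 0.20) and the lipid receptor gene Trem2 (2.46 ± 0.35). Of 19 cytokine and chemokine genes 13 rose and 16 did so adjusted over the list alone, including Il1rn, which encodes the antagonist of the interleukin 1 receptor (4.01 ± 0.44), and the monocyte attractant genes Ccl2 (2.76 ± 0.31) and Ccl7 (2.10 ± 0.28). Of 17 matrix protease genes 6 rose, including Mmp13 (7.18 ± 0.96, adjusted p = 0.0015) and the macrophage elastase gene Mmp12 (5.01 ± 0.70, adjusted p = 0.0019). Mmp13 was not called with limma-voom (7.18, adjusted p = 0.079). Neither Mmp13 (0.059) nor Mmp12 (0.088) was called in the NovaSeq samples alone, nor were most genes printed for this comparison, such as Trem2 (0.078), Icos (0.064), Tnf (0.16), Hmox1 (0.064) and Ccna2 (0.18). Of the 59 called genes that the naming rule gave, 14 were called there, from 2 samples per group. Between samples of the same number, read as paired, the neutrophil index was higher with verteporfin by 0.27, 0.37 and 0.26. The myelin (-1.11, -0.16 and -0.18) and pan-Schwann indices (-1.04, -0.23 and -0.37) were lower in each pair. With 3 pairs the exact permutation p was 0.25 for each, the smallest it can be, so a change in these lists stays open. The 0 called genes do not bound its size, since the gene test recovered 25 of 100 simulated 2-fold changes in this comparison. Of 15 repair Schwann cell genes 2 rose, Runx2 (0.89 ± 0.21, adjusted p = 0.031) and the injury factor gene Atf3 (1.18 ± 0.28, 0.034), in a list that did not pass (0.82). Runx2 lost its call without any of the 6 libraries (0.052 to 0.13). Atf3 lost its call without CC4:2 replicate 2 (0.12) or 3 (0.09) or VP4:2 replicate 1 (0.11) or 3 (0.12), and ran from 0.99 to 1.56 with a library left out.

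The macrophage list had an adjusted p of 5.9e-16 and kept its call with an estimated correlation (adjusted p = 0.04), the 1 list in any comparison to do so. The other lists that passed lost theirs, with an adjusted p = 0.13 with an estimated correlation for cytokines (preset 6.0e-14) and an adjusted p = 0.77 with an estimated correlation for matrix proteases (preset 0.0085). Of 15 T and NK cell markers 5 rose and 12 adjusted over the list alone, including Cd3e (2.44 ± 0.38) and Icos (2.77 ± 0.43; list adjusted p = 1.2e-08, and adjusted p = 0.26 with an estimated correlation). Of 12 B and plasma cell markers 2 rose and 8 adjusted over the list alone (1.3e-04, and adjusted p = 0.65 with an estimated correlation). Immunoglobulin genes took 0.14%, 1.46% and 0.78% of the counts in VP4:2. Of 23 cell cycle genes 6 rose and 18 adjusted over the list alone, such as Ccna2, the cyclin A gene (1.41 ± 0.25; list adjusted p = 3.4e-08, and adjusted p = 0.34 with an estimated correlation). Of 11 genes of the NRF2 and haem response 3 rose, with Hmox1 at 1.71 ± 0.21 (0.0075, and adjusted p = 0.13 with an estimated correlation). Of 19 pain genes 5 rose, including Tnf (1.73 ± 0.28) and the purinergic channel gene P2rx4 (1.38 ± 0.18; 0.036, and adjusted p = 0.17 with an estimated correlation), and without VP4:2 replicate 1 the list stood at 0.053. Lists with at most 1 called member also passed, downward for perineurial (0.022, and adjusted p = 0.17 with an estimated correlation), nerve fibroblast (0.036, and 0.65 likewise) and endothelial markers (0.037, and 0.82 likewise), and upward for oxidative phosphorylation (0.024, and 0.73 likewise). Nerve fibroblast and endothelial markers lost the call without CC4:2 replicate 2 (0.15 and 0.34), CC4:2 replicate 3 (0.087 for both) or VP4:2 replicate 1 (0.093 and 0.094), and oxidative phosphorylation without CC4:2 replicate 3 (0.087) or VP4:2 replicate 1 (0.093). Of 19 cholesterol and fatty acid genes 2 fell, among them the sterol synthesis gene Lss (-0.85 ± 0.20), and 10 adjusted over the list alone (2.1e-05, and adjusted p = 0.32 with an estimated correlation). Lss lost its call without CC4:2 replicate 1 (0.095) or 2 (0.098), without VP4:2 replicate 1 (0.064), 2 (0.1) or 3 (0.11), and with the replicate number as a block (-0.85, adjusted p = 0.069).

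The edgeR test called 979 genes, 822 higher and 157 lower with verteporfin. With the replicate number as a block it called 853, 748 higher and 105 lower, of which 788 were among the 979. With platform as a covariate it called 884, of which 840 were among the 979. Large rises beside Mmp13 lay in Ankrd34c (5.55 ± 0.94) and Plppr4 (5.32 ± 0.73), and included Dcstamp (4.80 ± 0.65) and Ocstamp (4.66 ± 0.72), whose products act in the fusion of osteoclasts and macrophages. The largest falls lay in the neurofilament gene Nefl (-6.41 ± 1.40, adjusted p = 0.022, from 17.5 ± 22.2 to 0.199 ± 0.0317 CPM), the granin gene Scg2 (-4.16 ± 0.95), the cartilage protein gene Cilp2 (-3.05 ± 0.75) and the pacemaker channel gene Hcn4 (-2.98 ± 0.78). Of the 10 largest falls, only Islr2 (-2.64 ± 0.38), Cdhr1 (-2.27 ± 0.39) and Depp1 (-2.08 ± 0.26) kept their call with each library left out in turn. Nefl lost it without CC4:2 replicate 1 (0.058) or VP4:2 replicate 1 (0.09), 2 (0.076) or 3 (0.11). Scg2 lost it without each of the 6 libraries but CC4:2 replicate 1 (0.061 to 0.11). Cilp2 lost it without each but CC4:2 replicate 1 (0.066 to 0.16) and Hcn4 without any of the 6 (0.078 to 0.17). With a library left out Nefl ran from -6.98 to -4.59 and Cilp2 from -3.53 to -2.24. With the replicate number as a block Nefl (-5.93, adjusted p = 0.057), Cilp2 (-2.97, 0.086) and Hcn4 (-2.93, 0.082) were not called either. The list of neuronal and axonal transcripts did not pass (1 higher and 2 lower of 12, adjusted p = 0.37). Its member Stmn2 rose by 1.88 ± 0.44 (adjusted p = 0.031), a call lost without each library but CC4:2 replicate 1 (0.072 to 0.12), with values from 1.61 to 2.44. Of the 979 calls, 411 were made with each of the 6 libraries left out in turn, 392 higher and 19 lower, and of the 59 called genes that the naming rule gave, 29. Across all 19 settings tried, those calls that were kept numbered 165 of the 979 and 12 of the 59.

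Yap1 (-0.30 ± 0.20, adjusted p = 0.41), Wwtr1 (-0.37 ± 0.24, 0.39), Ccn1 (0.58 ± 0.54, 0.55), Ccn2 (0.95 ± 0.46, 0.26) and Ankrd1 (1.03 ± 1.01, 0.59) were not called with verteporfin. Of 21 YAP/TAZ-TEAD target genes 1 fell, Rbms3 (-0.71 ± 0.19, adjusted p = 0.049), and 0 rose, while 2 rose and 2 fell adjusted over the list alone (list adjusted p = 0.15). Rbms3 lost its call without any of the 6 libraries (0.073 to 0.16). The target score was 5.76 ± 0.17 with verteporfin and 5.87 ± 0.18 without (SD, n = 3; difference -0.11, exact two-sided permutation p = 0.5). Read as paired, the differences were 0.22, -0.32 and -0.23 (exact permutation p = 0.5). Of 19 Hippo pathway components 0 were called (list adjusted p = 0.13). Their index was lower with verteporfin in each pair (-0.15, -0.10 and -0.26, exact permutation p = 0.25, the smallest that 3 pairs can give), so a change stays open. The secreted factor gene Tgfb1 rose by 0.86 ± 0.14 (adjusted p = 0.0047) and its receptor gene Tgfbr1 by 1.42 ± 0.27 (0.01), while Ltbp1, which encodes a binding protein of latent TGF-beta, fell by 1.31 ± 0.30 (0.03), in a TGF-beta list that did not pass (0.79). In the NovaSeq samples alone none of Tgfb1 (0.14), Tgfbr1 (0.2) and Ltbp1 (0.36) was called. Ltbp1 lost its call without CC4:2 replicate 2 (0.087) or 3 (0.081), without VP4:2 replicate 1 (0.097), 2 (0.08) or 3 (0.12), and with the replicate number as a block (-1.29, adjusted p = 0.056). The NovaSeq samples alone gave 194 higher and 8 lower genes, 187 of them among the 979, and in VP4:2 against CC4:2 DESeq2 gave 1319 higher and 542 lower. Without CC4:2 replicate 1 the count was 652, without CC4:2 replicate 2 it was 550, without VP4:2 replicate 1 it was 545 and without VP4:2 replicate 3 it was 468.

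**Figure D3:**
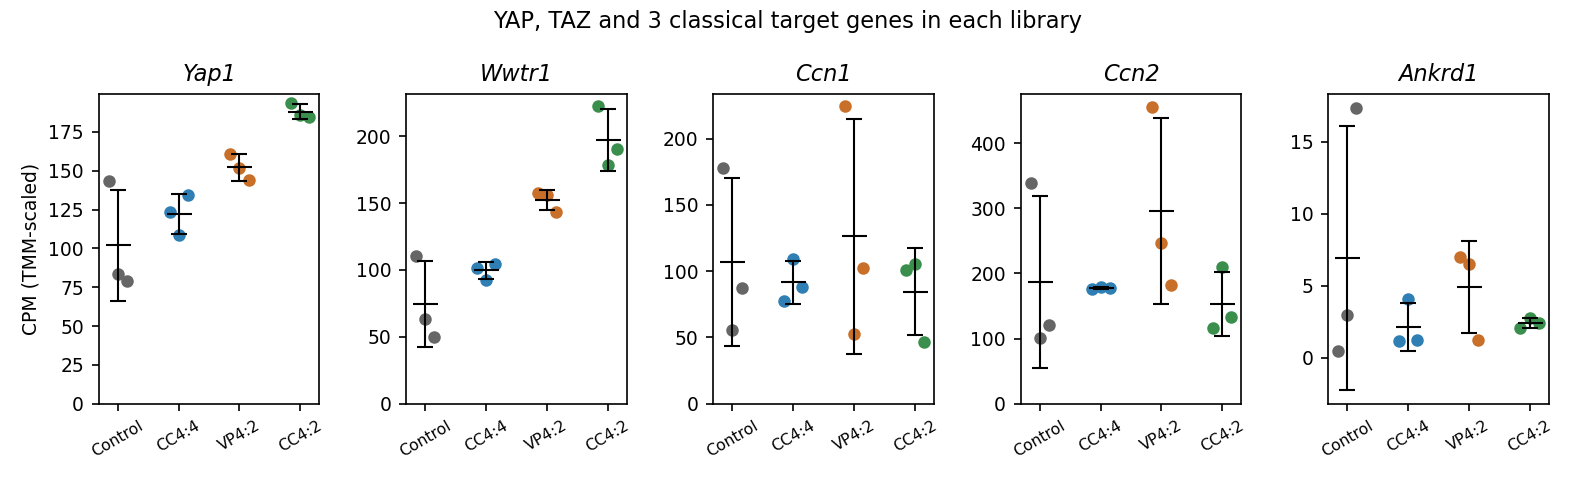
Points are TMM-scaled CPM of each library (vertical axis, linear), with the mean and SD of the 3 libraries of a group. Yap1 averaged 102 CPM in Control, 122 in CC4:4, 152 in VP4:2 and 188 in CC4:2, while Ccn2 averaged 187, 177, 295 and 153.

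Against control stumps, verteporfin-loaded stumps had higher Schwann cell, myelin and fat cell transcripts and lower neutrophil transcripts, as CC4:2 stumps did, while macrophage transcripts lay near Control. Of 17 myelin genes 15 rose (median 2.51), as did 5 of 10 pan-Schwann markers and 9 of 12 adipocyte markers, with Pmp22 at 2.45 ± 0.50 (adjusted p = 0.011), S100b at 2.58 ± 0.48 and Lep at 3.87 ± 0.72. Without Control replicate 1 the myelin index difference went from 2.95 to 1.98 and the pan-Schwann difference from 2.50 to 1.71, and with a library left out Pmp22 ran from 2.03 to 3.07. Of 9 neutrophil markers 8 fell and Mpo rose by 2.68 (adjusted p = 0.032), a call lost without Control replicate 1 (0.061), 2 (0.073) or 3 (0.098) or VP4:2 replicate 2 (0.087) or 3 (0.079), with S100a9 at -5.60 ± 0.54 (adjusted p = 9.0e-04) and Csf3r at -4.13 ± 0.33. Of 20 macrophage markers 2 fell and 18 were not called (median -0.10, list adjusted p = 0.37), and their mean log2 CPM was 7.98 ± 0.14 in VP4:2 and 8.12 ± 0.10 in Control. Of 15 T and NK cell markers 13 fell, such as Cd8a (-2.37 ± 0.41), and of 12 B and plasma cell markers 10 fell, such as Cd79a (-3.05 ± 0.63). Of 19 cytokine and chemokine genes 13 fell and 1 rose, with Cxcl2 at -7.09 ± 0.58 and Il1b at -4.44 ± 0.42.

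The camera lists gave adjusted p of 4.8e-09 for myelin, 1.6e-05 for pan-Schwann markers and 2.2e-06 for adipocytes, each with an adjusted p = 0.42 with an estimated correlation. The neutrophil list had 6.3e-08 (adjusted p = 0.11 with an estimated correlation), T and NK cells 3.3e-07 (0.37 likewise), B and plasma cells 2.2e-05 (0.43 likewise) and cytokines 3.4e-09 (0.35 likewise). Cholesterol and fatty acid genes also passed upward (11 higher and 1 lower of 19, 6.2e-07, and 0.35 likewise), as did repair Schwann cell genes (5 higher and 1 lower of 15, 0.0098, and 0.37 likewise), and cell cycle genes passed downward (3 lower of 23, 0.0016, and 0.53 likewise). The macrophage genes that fell were Adgre1 (-1.46 ± 0.36, adjusted p = 0.021) and Arg1 (-2.19 ± 0.56, 0.024). Adgre1 lost its call without Control replicate 2 (0.059) or VP4:2 replicate 1 (0.077), 2 (0.065) or 3 (0.057), and Arg1 without VP4:2 replicate 1 (0.088) or 3 (0.081). With a library left out Adgre1 ran from -1.64 to -0.96 and Arg1 from -2.80 to -1.32. In the NovaSeq samples alone neither Adgre1 (0.1) nor Arg1 (0.19) was called. Mmp13 fell by 3.26 ± 0.75 and lost its call without VP4:2 replicate 1 (0.065), 2 (0.052) or 3 (0.055), and ran from -3.73 to -1.68 with a library left out. In the same list Mmp12 rose by 2.46 ± 0.62 (adjusted p = 0.022) and Timp3 by 1.15 ± 0.19 (0.0054), with 2 higher and 4 lower of 17 (list adjusted p = 0.96). Mmp12 lost its call without Control replicate 3 (0.078) or VP4:2 replicate 2 (0.053) or 3 (0.066), and none of Mmp13 (0.15), Mmp12 (0.24) and Timp3 (0.1) was called in the NovaSeq samples alone. Of 21 YAP/TAZ-TEAD targets 4 rose and 2 fell, and the target score was 0.31 higher in VP4:2 (exact two-sided permutation p = 0.3). Wwtr1 rose by 1.03 ± 0.24 (adjusted p = 0.017) but not without VP4:2 replicate 1 (0.055) or 2 (0.054) or in the NovaSeq samples alone (0.16), with values from 0.84 to 1.43 with a library left out, and Yap1 was not called (0.58 ± 0.20, 0.071). The edgeR test called 2965 genes, 1462 higher and 1503 lower. The NovaSeq samples alone gave 2 higher and 17 lower genes, all 19 of them among the 2965. Of the 96 called genes that the naming rule gave, 7 were called there, from 2 samples per group. Pmp22 (2.54, adjusted p = 0.14), S100b (2.65, 0.11), Lep (3.14, 0.14), Cd8a (-2.63, 0.072) and Cd79a (-2.69, 0.16) were not. With all 12 samples and platform as a covariate, 2649 genes were called, 2575 of them among the 2965. The count was 1169 without Control replicate 3, 1241, 1245 and 1642 without VP4:2 replicates 1, 2 and 3, 1913 with only the 6 samples compared and, in VP4:2 against Control, 1775 at least 2-fold. Of the 2965 calls, 920 were made with each of the 6 libraries left out in turn and 19 in all 19 settings.

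Across the 15712 genes, the changes with verteporfin ran against the changes with the CC4:2 conduit. Of the 822 genes that rose with verteporfin, 743 were among the 3645 that fell in CC4:2 against Control, where independent lists would share 191, and of the 157 that fell, 145 were among the 3186 that rose (31.8 for independent lists). The correlation of the fold changes across genes, which are not independent replicates, was -0.78 (jackknife SE 0.08), against -0.50 in 20 simulations of unchanged groups (-0.53 to -0.47). The covariance was -1.29, against a simulated -0.12. Both comparisons use the CC4:2 libraries, which were not split between them, so part of the excess may come from the shared libraries. With no library in common, VP4:2 minus CC4:4 correlated with CC4:2 minus Control at 0.80 with a slope of 0.51 over all 15712 genes, of which 78.2% had the same sign. Over the 6831 called genes the values were 0.86, 0.52 and 92.4%, but those genes were picked by 1 of the 2 differences. These values show that VP4:2 shared the direction of the conduit change. They do not test whether verteporfin ran against it. For the conduits against Control, the fold changes correlated at 0.27 (jackknife SE 0.25), below the 0.51 (0.49 to 0.54) of unchanged groups that share the controls, and the covariance was 0.24 against a simulated 0.12. The many changes of CC4:2, absent from the simulation, widen the spread on 1 side and lower the correlation. The lower correlation therefore does not show less agreement than in unchanged groups. With 0 genes called in CC4:4 no overlap of calls could be counted.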

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

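Tests of the adipocyte against endothelial lists, blood and a wrong label of Control replicate 1, and the settings with the muscle covariate and without immunoglobulin genes, were chosen after the results were seen. That Control replicate 1 stood apart in the principal components was also known before its removal was tested. The conduits differed from each other in their change against Control, since the direct test of CC4:2 against CC4:4 called 6157 genes. The change against Control also differed with and without verteporfin in the 4:2 conduit, where the direct test called 979 genes. No test of outlying samples was run.

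The pattern of higher Schwann cell, myelin and adipocyte transcripts with lower immune transcripts in CC4:2 than in Control was set against 3 technical explanations. With the immunoglobulin genes recognised by symbol left out of the library sizes and the test, 6792 genes were called. Any among the 4911 genes without a unique symbol stayed in, and that count does not measure the size of these changes. The median log2 fold change of all genes moved only from -0.045 to -0.03. The index differences were 3.43 for myelin genes and 3.18 for adipocyte markers, which argues against the immunoglobulin counts of the controls as the whole source. With the skeletal muscle list as a covariate, 7061 genes were called, a count that does not measure the size of these changes either. The muscle index differed between CC4:2 and Control by 1.63 (SE 3.31), so the covariate could take up little of a group difference. The test therefore does not decide on carried muscle. A lower share of immune cells alone would raise the markers of other cell types alike, but the adipocyte index rose above the endothelial index by 2.63 (SE 0.48). A difference in how much fat or distal nerve was dissected was not tested and may contribute, as may the conduit itself.

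Macrophage transcripts of VP4:2 lay near Control while neutrophil transcripts stayed low. Blood carried in the tissue would move red blood cell and neutrophil transcripts together, but between VP4:2 and Control the red blood cell difference lay 4.03 (SE 1.28) above the neutrophil difference. Of the way from CC4:2 back to Control, the macrophage index had gone 92.2% and the neutrophil index 8%, which restates the pattern and tests no explanation. A change in the kind of immune cell present, or in what macrophages express under verteporfin, may underlie this and was not tested.

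No gene was called between CC4:4 and Control by edgeR (0, with 831 at an unadjusted p under 0.05, 10 by DESeq2 and 0 by limma-voom). Without Control replicate 1, 306 genes were called, so the spread that this library adds may hide differences. A wrong label on a CC4:2 or VP4:2 library would give it their low neutrophil index, but its index of 4.73 lay 3.53 above the highest of theirs, which span 0.56, and near the 4.27 and 4.58 of the other controls. Its highest correlation with those libraries, 0.901, was within the 0.896 to 0.91 of the other controls and did not part the groups. Its correlations with the CC4:4 libraries, 0.931 to 0.957, lay within the 0.926 to 0.958 of the other controls with them. Yet each was above its own correlations with the other controls, 0.896 and 0.91, while Control replicates 2 and 3 correlated with each other at 0.956. Whether it is a CC4:4 library was not tested and stays open.

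Each comparison of 3 against 3 samples has 10 splits, so the share of splits with a result as large is never under 0.1. Every split but the real one mixes libraries of the 2 groups. A difference between the groups then widens the spread and lowers the number of genes called, so those gene counts cannot decide on chance. The real split was the only 1 of the 10 to give as many genes for CC4:2 against Control (6831, highest other 3), VP4:2 against CC4:2 (979, highest other 1), CC4:2 against CC4:4 (6157, highest other 0) and VP4:2 against Control (2965, highest other 0), and all 10, the real one included, gave at least as many for CC4:4 against Control (0, highest other 5). For VP4:2 against CC4:2, where replicate numbers were read as paired, the 3 other splits that part all 3 pairs gave at most 1 gene, and each mixes the 2 groups. For gene lists 2 of the 10 splits, the real one included, passed at least as many as the real one for CC4:2 against Control (17, highest other 17), VP4:2 against CC4:2 (13, highest other 15), CC4:2 against CC4:4 (15, highest other 15) and VP4:2 against Control (17, highest other 17), and 4, the real one included, for CC4:4 against Control (14, highest other 16).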

How the results depend on the processing

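The muscle covariate and the removal of immunoglobulin genes were chosen after seeing the data. The cause of each change below was not tested, except that fewer samples leave fewer degrees of freedom. Gene counts with a change of at least 2-fold were 4128 for CC4:2 against Control, 3590 for CC4:2 against CC4:4 and 1775 for VP4:2 against Control. Only the 6 samples compared gave 4359 for CC4:2 against Control and 1913 for VP4:2 against Control. NovaSeq samples alone gave 3222 for CC4:2 against Control, 202 for VP4:2 against CC4:2, 3233 for CC4:2 against CC4:4 and 19 for VP4:2 against Control. DESeq2 gave 10 for CC4:4 against Control and 1861 for VP4:2 against CC4:2. With 1 library left out, counts ran from 0 to 306 for CC4:4 against Control (306 without Control replicate 1), 468 to 749 for VP4:2 against CC4:2 (468 without VP4:2 replicate 3, 749 without CC4:2 replicate 3) and 1169 to 4290 for VP4:2 against Control (1169 without Control replicate 3, 4290 without Control replicate 1). Other settings stayed within 1.5 times the main count. Without Control replicate 1, 3 of the 6831 calls of CC4:2 against Control changed sign, and in the other settings 0 calls did.

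With an estimated correlation 0 lists passed for CC4:2 against Control, CC4:4 against Control, CC4:2 against CC4:4 and VP4:2 against Control, and 1 for VP4:2 against CC4:2. With fry 0 passed for CC4:4 against Control and 8 for VP4:2 against CC4:2. For CC4:2 against Control fry passed 19, among them all 17 camera lists in the same direction. For CC4:2 against CC4:4 it passed 16, among them 14 of the 15 camera lists. For VP4:2 against Control it passed 14, among them 13 of the 17. The list of myelin genes, CC4:4 against Control, turned without Control replicate 1 (adjusted p = 0.08), and with the other libraries left out its adjusted p ran from 1.9e-08 without Control replicate 2 to 0.089 without CC4:4 replicate 1.

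The uncalled genes Ccn1, Ccn2 and Ankrd1 changed sign. In CC4:2 against Control, with 1 library left out, Ccn1 ran from -0.63 to 0.23, Ccn2 from -0.58 to 0.47 and Ankrd1 from -2.07 to 0.54, and Ankrd1 was 0.54 in the NovaSeq samples. In CC4:4 against Control Ccn1 ran from -0.50 to 0.36, Ccn2 from -0.34 to 0.68 and Ankrd1 from -2.51 to 0.38. There Ccn2 was 0.16 with limma-voom, 0.08 with the replicate block and 0.08 with the muscle covariate, and Ankrd1 was 0.66 in the NovaSeq samples. In VP4:2 against CC4:2 Ccn1 ran from -0.13 to 0.95. In CC4:2 against CC4:4 Ccn1 ran from -0.31 to 0.17 and Ankrd1 from -0.14 to 1.00, with 0.12 and -0.13 in the NovaSeq samples. In VP4:2 against Control Ccn1 ran from -0.47 to 0.82 and Ankrd1 from -1.05 to 1.56, and Ankrd1 was 0.66 with limma-voom and 2.02 in the NovaSeq samples.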
